A study of Mus musculus with 8 samples.

How the data were processed

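RNA was measured in the ventral lobe of the prostate of male FVB mice aged 8 weeks. The labels put 4 arrays in a wild-type group and 4 in a group transgenic for the middle T antigen of polyoma virus, here called MT. Per the labels' protocols, total RNA was extracted with Trizol, cleaned on RNeasy columns, labelled with biotin and hybridised to Affymetrix arrays in a core facility. The labels do not say that the arrays of a group came from separate animals. The p-values of tests over arrays therefore measure the spread between these samples, which may be technical. Permutation tests that shuffle genes measure the spread over genes alone.

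The deposited values are on a log2 scale. They were made with RMA, which corrects background, normalizes by quantiles and summarises the probes of a probe set, per the submitters' processing notes. The version of RMA is not given in the sources used here. The 8 arrays had medians from 6.21 to 6.23, and the values spanned 2.47 to 14.27. All 8 columns of the value table were used as deposited, with no further scaling and no filter on low values. For arrays the number of replicates limits the precision, and no depth applies.

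The table held 22690 probe sets, of which 64 were controls. The platform annotation gave 20380 of them a single gene symbol, 691 several symbols and 1555 others no symbol. Of the 20380, 20351 had a gene identifier found in the mouse reference gene table, and this changed 0 symbols. Probe sets with several symbols or none were named for no gene. Where a gene had several single-symbol probe sets, as 4956 did, the probe set with the highest mean over the 8 arrays stood for it, which left 12393 genes. Among the named genes with other probe sets, 57 in number, 1 had a probe set that passed the threshold in the opposite direction, and 15 that passed had another that did not.

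Differences are MT minus wild type. The main test was a limma fit (lmFit and eBayes, default prior) on the log2 values of all 8 arrays with no covariate, two-sided, with Benjamini-Hochberg adjustment over the 12393 genes and a threshold of 0.05. A change of 2-fold means a log2 fold change of at least 1 in size. Every adjusted p given for a gene comes from this limma test. Gene lists, 38 in number with 635 entries of which 552 were measured, were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists. Camera compares a list with all other genes. It was repeated with the correlation estimated from the data, and that p is given beside each list whose call it ended. Numbers of members past the threshold are given over all genes and adjusted over the list alone. RNA quality was read from control probe sets along Gapdh and Actb, as the 3' minus the 5' log2 value, with a two-sided exact permutation test over the 70 assignments of arrays to groups, whose smallest p is 0.0286. The versions were R 4.3.3, limma 3.58.1, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

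The design, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule took the 12 largest rises and the 12 largest falls among genes past the threshold whose groups did not overlap. It also took up to 4 members of each main or quality list and up to 2 of each cell type list with the largest changes past the threshold. In a list with none it took the member with the highest mean. It added 14 fixed genes, of which 10 had a probe set annotated to them alone. This named 128 genes. Genes outside the rule are marked as chosen after their values were seen.

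The sample titles number the arrays 1 to 4 in each group. Arrays with the same number deviated together from their group means. Across genes, the 4 correlations between same-numbered arrays ran from 0.10 to 0.18, all over 0.1, and each of the 8 arrays correlated best with its own number. Other pairs had a mean of -0.05, which is no separate baseline, since deviations from a group mean sum to 0. The numbers were therefore treated as pairs in checks beside the main tests, which used no pairing. This reading comes from the data, since no label states a shared litter, day or batch. The fit with the number as a replicate block was run as an alternative. The other alternatives were another prior, array weights, other rules for probe sets, a filter at the median level, renewed scaling, stricter thresholds, other list tests and leaving out each array in turn. Leaving out wild-type array 4 and MT array 2 was added after seeing the data, as were the p-values of single lists under another prior, array weights, unique-type probe sets and renewed scaling, and exact tests over the sign changes of the differences between same-numbered arrays.

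The fit was tested on 10 simulated sets with the real means and spreads and 200 changed genes each. For the comparison of MT with wild type over 12393 genes it recovered 72.7% of genes changed by 0.5 on the log2 scale, 97.5% of those changed by 1 and 99.8% of those changed by 2. False calls made up 5.0% of its calls. A list shifted by 0.5 was called in 10 of 10 sets, and 0 of 370 unshifted lists were called. Simulated genes were independent, unlike real ones. The 200 changed genes per set were also far fewer than the 5088 that passed in the real data. The adjustment depends on that share, so these rates need not hold for the real comparison.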

Results

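Gene expression was measured in the ventral prostate of male FVB mice at 8 weeks of age, on 4 arrays from wild-type mice and 4 arrays from mice carrying the polyoma virus middle T antigen. Middle T is a membrane-bound viral oncoprotein that engages Src-family kinases, phosphatidylinositol 3-kinase and the adaptor Shc. The design compares normal prostate with the prostate cancer that the transgene induces. All levels are log2 values after RMA, and every difference is MT minus wild type. Values are given as mean ± SD with n = 4 arrays per group, and errors of log2 fold changes are standard errors of the limma fit.

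The MT prostate differed from the wild-type prostate at a large share of genes. Of 12393 genes tested, 2447 were higher and 2641 were lower in MT at an adjusted p under 0.05, together 5088 genes or 41.1%. The change was at least 2-fold for 351 of the higher and 279 of the lower genes, and at least 4-fold for 81 and 44. The 4 MT values lay wholly on one side of the 4 wild-type values for 4961 genes, 40.0% of those tested, where chance gives 2.86%. The first principal component held 80.1% of the variance and separated the groups. Arrays correlated across genes at 0.996 to 0.997 within MT, at 0.992 to 0.994 within wild type and at 0.963 to 0.969 between groups. At a test against a minimum log2 change of 0.5 (limma treat), 877 genes passed.

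The largest rises were in chemokines and interferon-induced genes. Cxcl5, a chemokine that attracts neutrophils, rose from 3.62 ± 0.30 in wild type to 10.51 ± 0.13 in MT, and Cxcl2, of the same family of chemokines, rose from 3.49 ± 0.22 in wild type. Cxcl15 and Cxcl1 of that family rose by 5.91 ± 0.13 and 5.57 ± 0.08 on the log2 scale. The interferon-induced genes Oasl2 (5.33 ± 0.25), Ifit3 (4.48 ± 0.17), Usp18 (4.43 ± 0.21), Ifit1 (4.34 ± 0.14), Rtp4 (4.28 ± 0.22) and Irf7 (4.10 ± 0.23) followed, with Rtp4 at 2.80 when averaged over its probe sets. Lcn2 and Ltf, which encode iron-binding antimicrobial proteins, rose by 4.12 ± 0.13 and 4.05 ± 0.22. Adjusted p-values of these 12 genes ran from 9.39e-12 to 1.98e-07. Control probe sets for bacterial transcripts read from 2.57 to 3.90 over the arrays, and the mean wild-type levels of Cxcl5 and Cxcl2 lay within that background range. Set against the higher of the gene's own value and the highest such control on each wild-type array, Cxcl5 was at least 111-fold and Cxcl2 at least 79.0-fold higher. On their own arrays, 2 of 4 wild-type values of Cxcl5 and 3 of 4 of Cxcl2 were no higher than that control. Such bounds, here and below, use group means and do not allow for the spread between arrays.

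The 12 largest falls were led by Ibsp and Pbsn. Ibsp, bone sialoprotein, fell from 8.34 ± 0.43 to 3.23 ± 0.14, within the background range on 4 of 4 MT arrays, so that it was at least 26.6-fold lower. Pbsn, the androgen-regulated secretory protein probasin, fell from 13.28 ± 0.38 to 9.12 ± 0.68, a 17.8-fold difference, and the secreted trypsin inhibitor Spink1 fell from 13.81 ± 0.06 to 10.77 ± 0.18. Tph1, the first enzyme of serotonin synthesis, had a log2 fold change of -3.88 ± 0.39, and Tac1, the precursor of substance P, one of -3.61 ± 0.17. The beta-defensins Defb1 (-3.31 ± 0.34) and Defb10 (-3.04 ± 0.15) and the calcium channel Trpv6 (-3.07 ± 0.11) fell as well. Crabp1 (-3.02 ± 0.15), Mgll (-3.01 ± 0.20), Pik3c2g (-2.99 ± 0.11) and Cela1 (-2.89 ± 0.11) completed the 12, with adjusted p-values of all 12 from 2.75e-09 to 1.63e-05. The probe set of Mgll decided its call: among probe sets of the unique type alone, Mgll had a log2 fold change of -0.15 (adjusted p = 0.208).

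**Figure D1:**
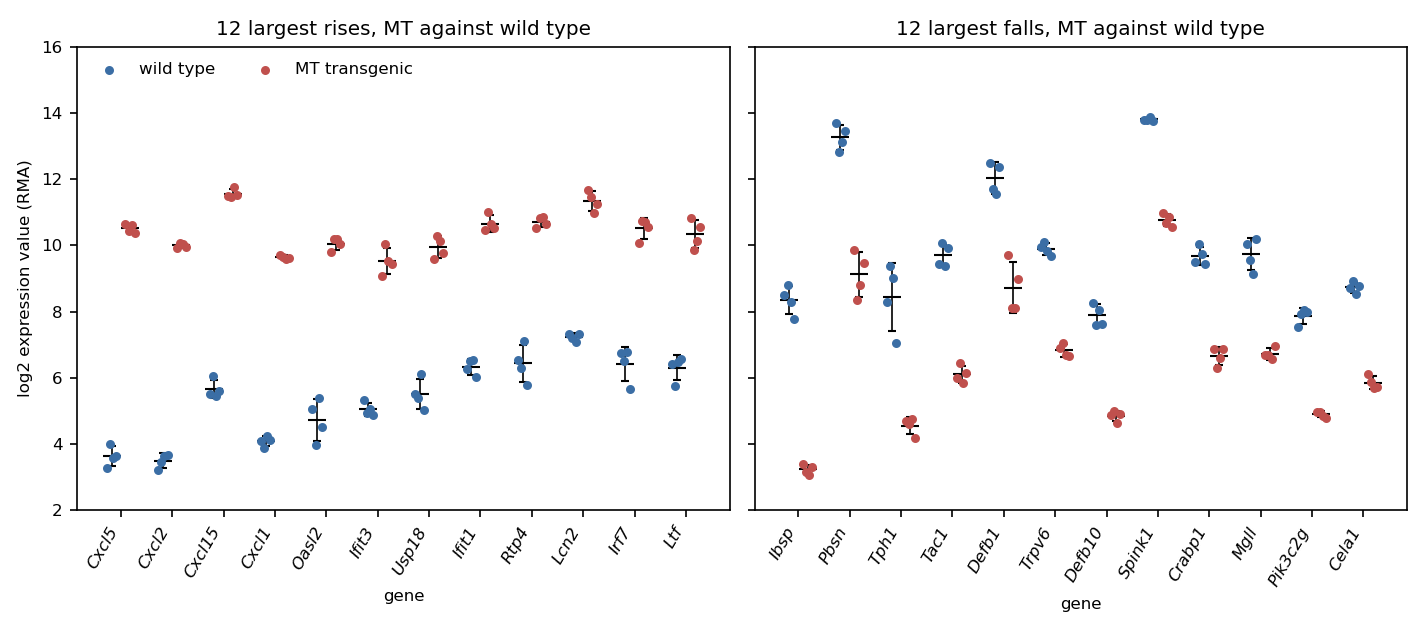
Log2 expression values (y axis) of the 12 genes with the largest rises and the 12 with the largest falls (x axis), for each of 4 wild-type arrays (blue) and 4 MT arrays (red), with the mean and SD as black bars. The groups do not overlap for any of the 24 genes, as the rule that chose them required, and Cxcl5 rises from 3.62 to 10.51 while Ibsp falls from 8.34 to 3.23.

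Interferon-response genes rose together. All 19 measured members of the list rose (19 adjusted over the list alone), with a median log2 fold change of 1.65 and a range from 0.60 to 5.33 (camera adjusted p = 2.28e-15; adjusted p = 0.145 with an estimated correlation). Their mean level was between 5.95 and 6.22 on the wild-type arrays and between 8.17 and 8.73 on the MT arrays. Genes of antigen presentation rose with them: 11 of 15 passed the threshold, all higher (12 adjusted over the list alone), with a median of 1.45 (camera adjusted p = 3.36e-08; adjusted p = 0.145 with an estimated correlation). The immunoproteasome subunits Psmb8 and Psmb9 rose by 2.34 ± 0.10 and 1.78 ± 0.12. The class I gene H2-K1 rose from 11.90 ± 0.11 to 13.69 ± 0.04, and the class II gene H2-Aa by 1.87 ± 0.21. Macrophage genes were higher in the same arrays, with a median of 0.51.

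Chemokine and cytokine genes moved mostly upward, with 16 of 27 higher and 1 lower (16 and 1 adjusted over the list alone). Their median was 0.53, their mean 1.31 (camera adjusted p = 4.26e-07), and the call held with an estimated correlation (adjusted p = 0.0231). Il33, the one member that fell (-1.07 ± 0.23), and Ccl20 (2.43 ± 0.17), which attracts cells bearing Ccr6, were chosen after their values were seen. In the list of complement and acute-phase genes, 8 of 15 were higher and 4 lower, with the same counts adjusted over the list alone, and the list itself did not pass (median 0.30, camera adjusted p = 0.0747), though it did without wild-type array 4 (adjusted p = 0.0357) and with median centring (adjusted p = 0.0423). The acute-phase gene Saa1 rose by 2.93 ± 0.27 and Cd55, which restrains complement on the cell surface, by 1.92 ± 0.15.

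Among the lists of leukocyte markers, that of macrophages had the most members past the threshold. Of 16 macrophage genes, 10 were higher and 1 lower (11 and 1 adjusted over the list alone), with a median of 0.51 (camera adjusted p = 0.000196; adjusted p = 0.406 with an estimated correlation). The protease Ctss rose by 2.40 ± 0.18 and the lipopolysaccharide co-receptor Cd14 by 1.30 ± 0.09. For Lyz2 and Csf1r, chosen after their values were seen, the differences were 0.28 ± 0.25 (adjusted p = 0.416) and 0.32 ± 0.13 (adjusted p = 0.0708). Of 9 granulocyte genes, 3 were higher by either adjustment (3 adjusted over the list alone; median 0.15, camera adjusted p = 0.00901). The estimated correlation ended that call (adjusted p = 0.406). S100a8 and S100a9, calcium-binding proteins of neutrophils that other cells can also make, both rose, S100a8 by 3.33 ± 0.14. S100a9, whose mean wild-type level (3.69 ± 0.18) lay within the background range, with 2 of 4 arrays no higher than their highest control, was at least 6.33-fold higher. The T cell list (3 higher and 1 lower of 10, 4 adjusted over the list alone) and the list of B and plasma cells (1 higher of 9, 1 adjusted over the list alone) did not pass, at camera adjusted p-values of 0.479 and 0.136. Cd3g, at a wild-type level within the background range (3.70 ± 0.19), was at least 1.68-fold higher by the means of all arrays, or 0.75 on the log2 scale. Of its 4 wild-type values, 1 was no higher than the highest control of its array. Without MT array 2 its log2 difference was 0.50 (adjusted p = 0.00582), below that bound, against 0.76 ± 0.21 with all arrays. Cd4 rose by 0.28 ± 0.06, and Jchain, the joining chain of secreted immunoglobulins, by 2.97 ± 0.25. Averaged over its probe sets, Cd4 had a difference of 0.13 (adjusted p = 0.0613). None of 8 mast cell genes passed in limma, at an unadjusted p under 0.05 for 2 of them (0 adjusted over the list alone, camera adjusted p = 0.888). The mast cell gene with the highest level, Tpsb2, had a difference of -0.06 ± 0.07 (adjusted p = 0.516). Among probe sets of the unique type it was 0.21 higher in MT (adjusted p = 0.0352).

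Cell cycle genes rose. Of 36 proliferation genes, 30 were higher and 0 lower (32 higher and 1 lower adjusted over the list alone), with a median log2 fold change of 0.96 (camera adjusted p = 1.22e-15). The call held with an estimated correlation (adjusted p = 0.0231). Markers of cell types moved too, with luminal keratin and adhesion genes higher for 16 of 18 and smooth muscle genes lower for 11 of 11. Whether cell make-up had a part in the rise was not tested. Mki67, a marker of cycling cells, rose from 5.44 ± 0.32 to 7.87 ± 0.19, and Birc5, Ube2c and Mcm6 rose by 2.25 ± 0.14, 2.21 ± 0.12 and 2.00 ± 0.26. The inhibitor of cyclin-dependent kinases Cdkn1b also rose, by 1.25 ± 0.12, and Cdkn1a rose by 0.47 ± 0.16 (adjusted p = 0.0386). The Cdkn1a call was lost without any of 5 arrays left out singly, namely wild-type arrays 1, 2 and 3 and MT arrays 1 and 4, at adjusted p-values from 0.0813 to 0.112, and with another prior (adjusted p = 0.0544). Cdkn2a differed by 0.24 ± 0.12 (adjusted p = 0.142). Rb1 fell by 0.46 on the log2 scale, with a standard error of 0.13 (adjusted p = 0.0141), a call lost without wild-type array 4 and MT array 2 together (-0.30, adjusted p = 0.0631).

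The list of glycolysis and hypoxia genes was higher in MT, with 14 of 19 higher and 2 lower (14 and 2 adjusted over the list alone) and a median of 0.59 (camera adjusted p = 8.61e-06). The adjusted p was 0.228 with an estimated correlation. Luminal keratin and adhesion genes (16 of 18) and macrophage genes (10 of 16) were higher too, and smooth muscle genes were lower (11 of 11). Whether cell make-up had a part in the rise was not tested. The oxygen-responsive gene Egln3 rose by 1.34 ± 0.09, the lactate transporter Slc16a3 by 1.19 ± 0.13, and the glycolytic enzymes Tpi1 and Pfkl by 1.07 ± 0.07 and 0.90 ± 0.09. The 2 that fell, Vegfa (-0.35 ± 0.12) and Adm (-0.45 ± 0.11), are induced by hypoxia. So are the 3 that did not pass, Car9 (-0.06 ± 0.11), P4ha1 (0.10 ± 0.15) and Slc2a1 (0.07 ± 0.11). These 5 genes were chosen after their values were seen, as all the members that did not rise past the threshold. The 14 that rose also hold genes that hypoxia induces, Egln3 among them. Genes of oxidative phosphorylation went both ways, with 7 higher and 7 lower of 30 (14 adjusted over the list alone) and a median of -0.02 (camera adjusted p = 0.982). Idh3a (0.57 ± 0.08, or 0.31 among probe sets of the unique type) and Mdh2 (0.39 ± 0.09) rose, while Uqcrfs1 (-0.55 ± 0.06) and Ndufa1 (-0.48 ± 0.06) fell.

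Neither list for the pathways that middle T engages passed, while single members changed. Of 18 genes that report ERK signalling, 5 were higher and 1 lower (5 adjusted over the list alone), and the list did not pass (median 0.09, camera adjusted p = 0.0808). It did pass without wild-type array 4 (adjusted p = 0.0362). The transcription factor Egr1 rose from 6.13 ± 0.65 to 9.39 ± 0.13, and Ier3, Spry1 and Dusp6 rose by 1.33 ± 0.13, 1.21 ± 0.10 and 1.04 ± 0.14. Spry1 and Dusp6 encode feedback inhibitors of the pathway. Myc differed by 0.01 ± 0.07 (adjusted p = 0.917). Of 19 FOXO targets, 6 were higher and 2 lower (9 adjusted over the list alone), with a median of 0.17 (camera adjusted p = 0.272). Klf15 fell (-1.63 ± 0.09), while Ccng2 (1.15 ± 0.12) and Gadd45a (1.00 ± 0.13) rose. Of the kinases and adaptors that middle T engages or acts through, Src rose by 0.27 ± 0.09 (adjusted p = 0.0305; 0.43 among probe sets of the unique type), Shc1 differed by 0.17 ± 0.07 (adjusted p = 0.0823), Akt1 by 0.12 ± 0.07 (adjusted p = 0.179) and Pik3ca by 0.01 ± 0.07 (adjusted p = 0.895). The Src call was lost without any of 6 arrays left out singly, all but wild-type array 4 and MT array 3, at adjusted p-values from 0.0567 to 0.0908. Its difference of 0.43 among probe sets of the unique type, with all arrays, had an adjusted p of 0.000855. The Shc1 difference passed without wild-type array 2 (adjusted p = 0.0189) and after renewed quantile normalization (adjusted p = 0.044).

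Immediate early genes rose as well, with 11 of 19 higher and 2 lower (11 and 2 adjusted over the list alone) and a median of 0.58 (camera adjusted p = 0.00025). The adjusted p was 0.0637 with an estimated correlation. Besides Egr1, Jun rose by 1.96 ± 0.14 and Fos by 1.92 ± 0.12, while Klf2 and Klf4, chosen after their values were seen, fell by 0.39 and 0.90 on the log2 scale. These genes also respond to handling of tissue. The heat shock gene Hspa1a was 1.42 ± 0.52 higher (adjusted p = 0.0487), with values from 7.16 to 9.44 in wild type and from 8.89 to 11.02 in MT. Its call was lost under another prior, array weights, probe set averaging, median centring and without single arrays, except wild-type arrays 1 and 2 and MT array 3, at adjusted p-values from 0.0513 to 0.151, and without wild-type array 4 and MT array 2 together (adjusted p = 0.229). The difference was 0.92 without wild-type array 4 and 0.75 without both of these arrays. Of 10 housekeeping genes, 5 were higher and 3 lower (8 adjusted over the list alone; median 0.17, camera adjusted p = 0.197), among them Tfrc (1.17 ± 0.15, or 0.64 averaged over probe sets), Gusb (0.95 ± 0.10), Ywhaz (0.71 ± 0.13) and Pgk1 (0.59 ± 0.07). Of 17 SREBP and lipid synthesis genes, 8 were higher and 2 lower (11 adjusted over the list alone; median 0.14, camera adjusted p = 0.197). The sterol synthesis genes Cyp51, Hmgcs1 and Idi1 rose by 1.07 ± 0.14 (0.45 averaged over probe sets), 0.63 ± 0.13 and 0.60 ± 0.12, and the desaturase Scd1 fell (-0.85 ± 0.10).

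**Figure D2:**
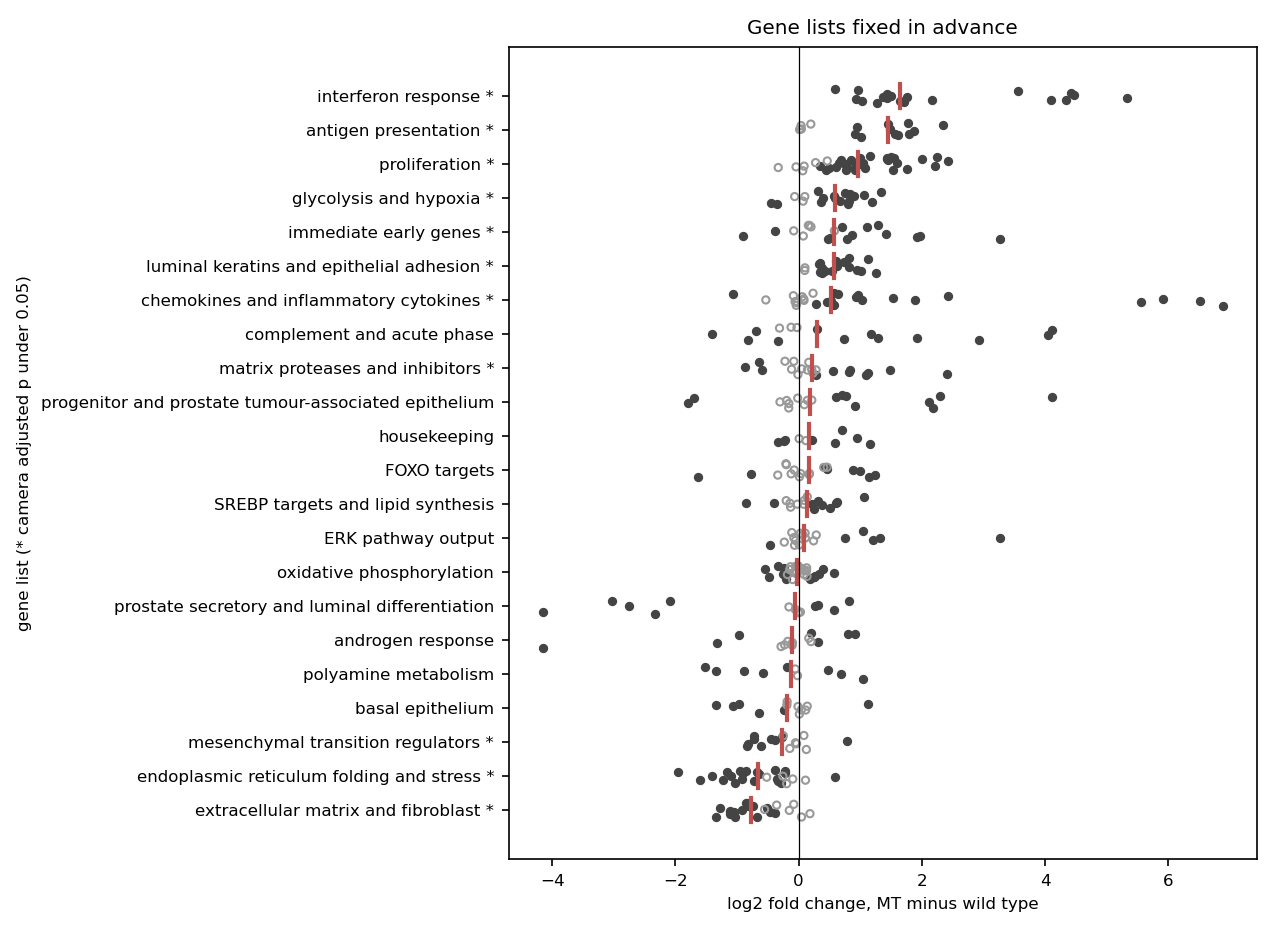
Log2 fold changes (x axis) of every measured member of the main and quality gene lists (y axis), filled where the gene passed an adjusted p of 0.05 and open where it did not, with the list median as a red bar and an asterisk where camera called the list. Interferon genes have the highest median, 1.65, and extracellular matrix and fibroblast genes the lowest, -0.78.

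Genes of the secretory luminal cell split. Of 13 measured prostate secretory and luminal genes, 5 fell and 4 rose (9 adjusted over the list alone), and the list did not pass (median -0.05, mean -0.97, camera adjusted p = 0.193). Besides Pbsn and Spink1, the secreted glycoprotein Azgp1 fell from 11.08 ± 0.21 to 8.33 ± 0.12 and the retinaldehyde dehydrogenase Aldh1a1 from 11.55 ± 0.15 to 9.22 ± 0.12. Androgen-response genes went both ways, with 4 higher and 3 lower of 14 (8 adjusted over the list alone; median -0.10, camera adjusted p = 0.696). Fkbp5 (-1.32 ± 0.08) and Tsc22d3 (-0.97 ± 0.07), both induced by steroid hormones, fell and Steap4 rose (0.91 ± 0.11). Luminal keratins and epithelial adhesion genes rose, 16 of 18 with 0 lower (16 adjusted over the list alone) and a median of 0.57 (camera adjusted p = 3.36e-08). Their adjusted p was 0.0872 with an estimated correlation. In the same arrays smooth muscle genes were lower for 11 of 11 (median -1.01) and extracellular matrix and fibroblast genes for 16 of 22 (median -0.78). Cldn4 rose by 1.26 ± 0.19, Cd24a by 1.13 ± 0.10, Krt8 by 1.01 ± 0.06 and Krt19 by 0.95 ± 0.11.

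Basal epithelial genes did not pass as a list, with 5 lower and 1 higher of 13 (6 adjusted over the list alone; median -0.19, camera adjusted p = 0.272). The basal keratins Krt15 (-1.35 ± 0.19) and Krt5 (-1.07 ± 0.12) and the basal transcription factor Trp63 (-0.98 ± 0.14, or -0.38 averaged over its probe sets) fell, and the integrin Itgb4 rose (1.13 ± 0.10). In the list of progenitor and tumour-associated epithelium, 8 of 18 were higher and 2 lower (10 adjusted over the list alone; median 0.18, camera adjusted p = 0.0747). The list passed with median centring (adjusted p = 0.0429). The transcription factor Sox4 rose by 2.30 ± 0.10, the adhesion receptor Cd44 by 2.19 ± 0.10 and the protease Ctse by 2.12 ± 0.22. Averaged over probe sets, Sox4 differed by 1.48 and Ctse by 1.28, and among probe sets of the unique type Ctse differed by 0.44. The 2 members that fell, Psca (-1.79 ± 0.10) and Agr2 (-1.69 ± 0.10), were chosen after their values were seen.

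Genes of protein folding in the endoplasmic reticulum fell. Of 26, 20 were lower and 1 higher (22 and 1 adjusted over the list alone), with a median of -0.66 (camera adjusted p = 3.36e-08). The adjusted p was 0.145 with an estimated correlation. Smooth muscle genes were lower too, for 11 of 11, and matrix and fibroblast genes for 16 of 22, while luminal keratin and adhesion genes were higher for 16 of 18. Whether cell make-up had a part in the fall was not tested. Sdf2l1 fell from 9.99 ± 0.24 to 8.03 ± 0.18 and Herpud1 from 12.04 ± 0.34 to 10.44 ± 0.06, and the oxidoreductases Ero1b and Pdia6 had log2 fold changes of -1.40 ± 0.15 and -1.24 ± 0.12. Polyamine genes went both ways, with 5 lower and 3 higher of 10 (8 adjusted over the list alone; median -0.12, camera adjusted p = 0.314). Odc1, the first enzyme of polyamine synthesis, fell from 11.18 ± 0.09 to 9.66 ± 0.09, and the spermidine synthase Srm and the regulator Azin1 fell too (-1.34 ± 0.105 and -0.88 ± 0.06). Smox, which oxidises spermine, rose by 1.05 ± 0.07.

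Stromal genes fell. All 11 smooth muscle genes were lower (11 adjusted over the list alone), with a median of -1.01 (camera adjusted p = 0.000132; adjusted p = 0.406 with an estimated correlation), among them Actg2 (-1.23 ± 0.29) and the myosin Myh11 (-1.16 ± 0.21, or -0.78 averaged over probe sets). Of 22 extracellular matrix and fibroblast genes, 16 were lower and 0 higher (17 adjusted over the list alone), with a median of -0.78 (camera adjusted p = 3.28e-05; adjusted p = 0.406 with an estimated correlation). The proteoglycans Dcn and Lum had log2 fold changes of -1.28 ± 0.09 and -1.12 ± 0.19, Mfap5 one of -1.34 ± 0.21 and the growth factor receptor Pdgfra one of -1.12 ± 0.19. The estimated correlations between genes were 0.84 in the smooth muscle list and 0.50 in the matrix list. Regulators of mesenchymal transition were lower for 8 of 15 and higher for 1 (9 and 1 adjusted over the list alone; median -0.27, camera adjusted p = 0.044; adjusted p = 0.406 with an estimated correlation). Prrx1 (-0.84 ± 0.12), Zeb1 (-0.82 ± 0.11, or -0.31 averaged over probe sets) and Vim (-0.73 ± 0.18) fell and Tgfb1 rose (0.78 ± 0.09). Matrix proteases and their inhibitors were higher for 8 of 21 and lower for 3 (11 and 3 adjusted over the list alone; median 0.21, camera adjusted p = 0.044; adjusted p = 0.406 with an estimated correlation). Besides Ctss, Mmp7 rose by 1.48 ± 0.27, Adam8 by 1.13 ± 0.14 and the inhibitor Timp2 by 1.09 ± 0.105 (0.44 averaged over probe sets). The calls of these 2 lists were also lost without single arrays: the mesenchymal list without wild-type array 3 (adjusted p = 0.0597), wild-type array 4 (0.067) or MT array 1 (0.0523), and the protease list without wild-type array 3 (0.0554) or MT array 3 (0.0574). Endothelial genes did not pass, with 2 of 13 lower (2 adjusted over the list alone; median -0.08, camera adjusted p = 0.54), namely Tek (-0.50 ± 0.12) and Cldn5 (-0.37 ± 0.07).

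**Figure D3:**
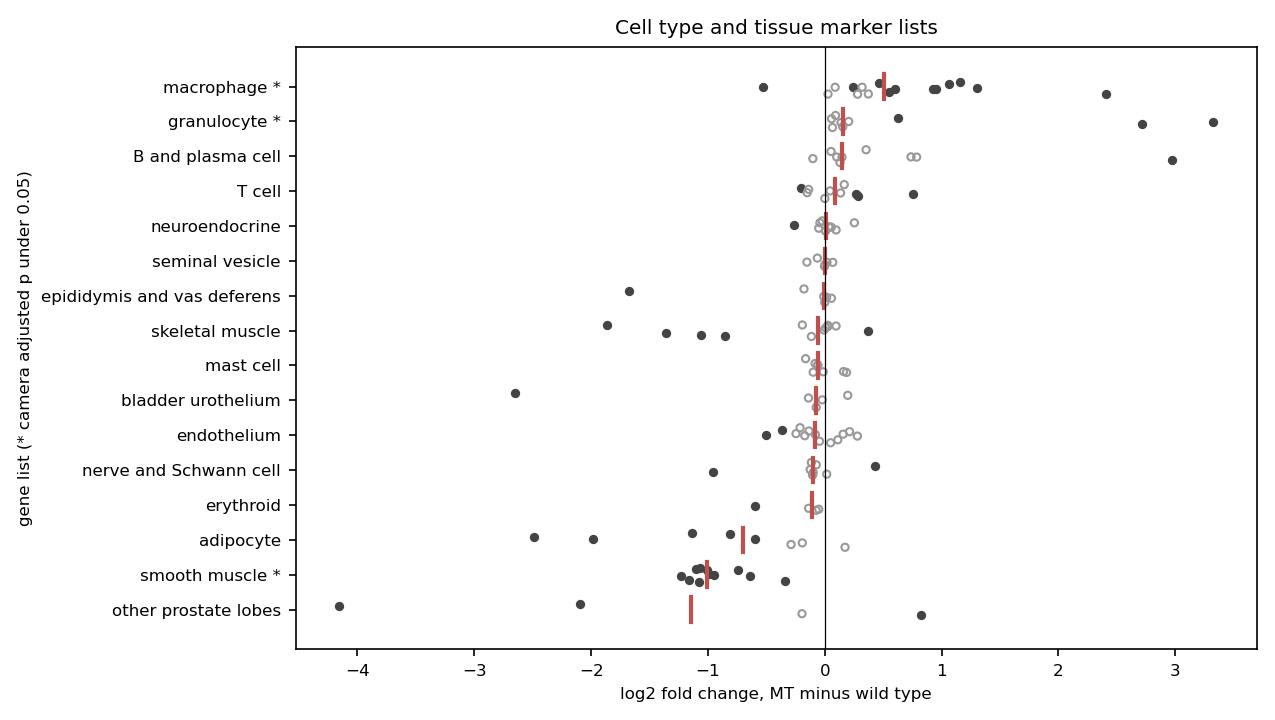
Log2 fold changes (x axis) of every measured member of the cell type and tissue lists (y axis), drawn as in the plot of the main lists. Smooth muscle genes lie below 0 throughout, with a median of -1.01, while endothelial genes lie around 0, with a median of -0.08.

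Adipocyte genes were uneven between arrays. Beside the stromal genes, 5 of 8 were lower in MT, but the list did not pass (5 adjusted over the list alone; median -0.70, camera adjusted p = 0.136). Their mean level ran from 6.08 to 7.73 on the wild-type arrays and from 5.79 to 6.40 on the MT arrays. The list passed without wild-type array 1 (adjusted p = 0.0248). Adipoq, the adipocyte hormone adiponectin, read 5.21, 7.26, 8.10 and 9.39 in wild type and 4.60, 6.70, 4.50 and 4.22 in MT (-2.49 ± 0.77, adjusted p = 0.0235). Fabp4 differed by -1.98 ± 0.54 (adjusted p = 0.0125). Both calls were lost with another prior, at adjusted p-values of 0.1 and 0.0676. The Adipoq call was also lost without any of 5 arrays left out singly, wild-type arrays 3 and 4 and MT arrays 1, 3 and 4, at 0.0579 to 0.0673. Among probe sets of the unique type, Fabp4 differed by -0.10 (adjusted p = 0.562), and averaged over its probe sets by -0.98. Without wild-type array 4 and MT array 2, the arrays of each group highest in adipocyte genes, 2047 genes were higher and 2127 lower, and 607 of the 4174 changed at least 2-fold.

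**Figure D4:**
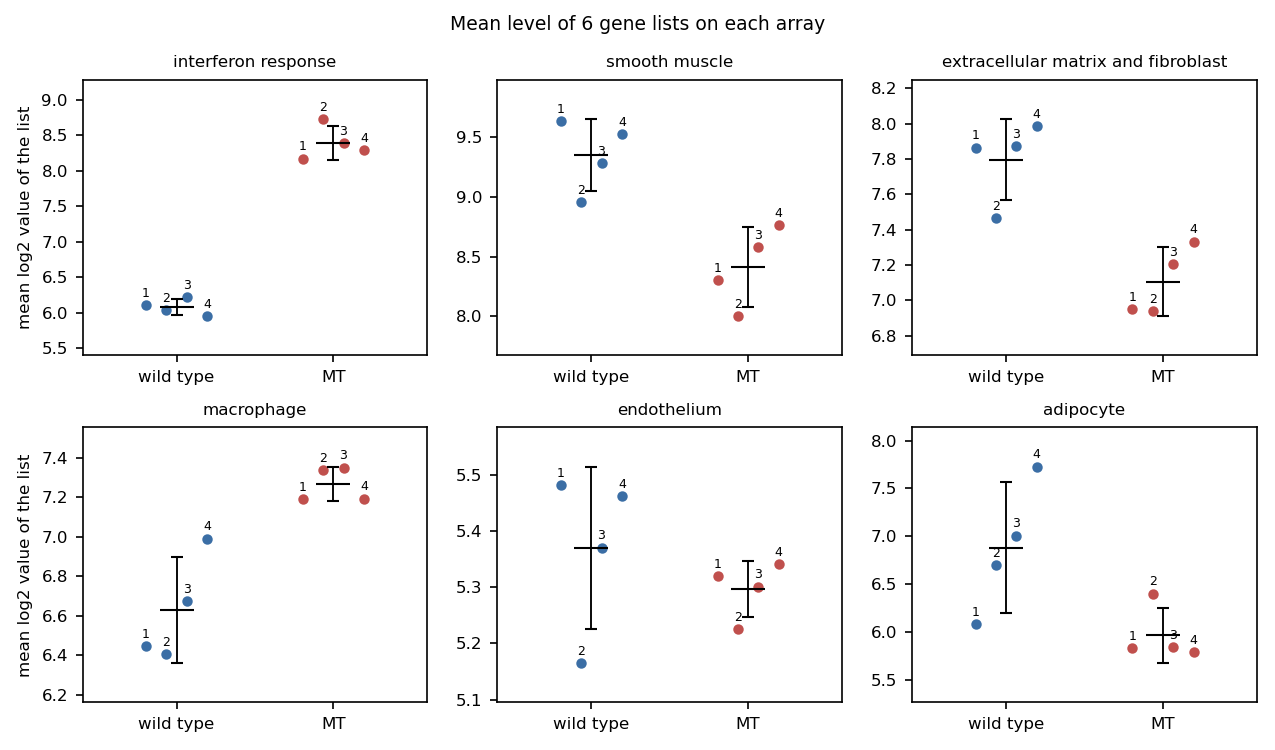
Mean log2 value (y axis, a scale for each panel) of 6 gene lists on each wild-type (blue) and MT (red) array (x axis), with replicate numbers above the points and the mean and SD of each group as black bars. Interferon genes lie between 5.95 and 6.22 in wild type and between 8.17 and 8.73 in MT, while adipocyte genes reach 7.73 on wild-type array 4 and 6.40 on MT array 2.

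Markers of neighbouring tissues mostly stayed under the threshold. Of 12 skeletal muscle genes, 4 were lower and 1 higher (5 adjusted over the list alone; median -0.06, camera adjusted p = 0.197), with Myh1 at -1.87 ± 0.15 and Tnnc2 at -1.36 ± 0.22. The Myh1 call rested on its probe set, since among probe sets of the unique type the difference was -0.20 (adjusted p = 0.107). In the bladder urothelium list only Upk1a passed, 1 of 5 (1 adjusted over the list alone; median -0.07, camera adjusted p = 0.349), with a fall from 11.22 ± 0.31 to 8.57 ± 0.31. In the list of epididymis and vas deferens it was Defb2, 1 of 6 (1 adjusted over the list alone; median 0.00, mean -0.30, camera adjusted p = 0.477), at -1.68 ± 0.12. Of 4 measured genes of other prostate lobes, 2 were lower and 1 higher (3 adjusted over the list alone; median -1.14, camera adjusted p = 0.314). The 2 that fell were Pbsn (-4.16 ± 0.29), which also stands in the secretory and androgen lists, and Msmb (-2.09 ± 0.36). Whether a different amount of other lobes in the pieces had a part in these falls was not tested. None of 6 seminal vesicle genes passed in limma, at an unadjusted p under 0.05 for 0 of them (0 adjusted over the list alone, camera adjusted p = 0.919), and Svs5 differed by 0.00 ± 0.10. Of 8 genes of nerve and Schwann cells, 1 was lower, Pmp22 (-0.96 ± 0.16), and 1 higher, Mbp (0.43 ± 0.07), with 2 adjusted over the list alone (median -0.10, camera adjusted p = 0.505). Another probe set of Mbp fell (-0.40), and its probe set average differed by -0.01 (adjusted p = 0.952). Chga alone passed of 9 neuroendocrine genes (-0.27 ± 0.07; 1 adjusted over the list alone; median 0.01, camera adjusted p = 0.982), and Alas2 of 4 erythroid genes (-0.60 ± 0.14; 1 adjusted over the list alone; median -0.11, camera adjusted p = 0.388).

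RNA quality, read along the control transcripts, did not differ past the threshold. The 3' minus 5' log2 value of Gapdh was 0.70 ± 0.17 in wild type and 0.51 ± 0.09 in MT (exact permutation p = 0.0857), and that of Actb was 0.91 ± 0.14 and 0.73 ± 0.12 (exact permutation p = 0.114). Both were lower in MT, by 0.19 and 0.18 on the log2 scale. The mean of 18 hybridisation control probe sets was 10.60 ± 0.26 in wild type and 10.25 ± 0.12 in MT (exact permutation p = 0.114). The control probe sets of Gapdh themselves were 1.09 higher in MT and those of Actb 0.36 higher (exact permutation p = 0.0286 for each, the smallest possible). With same-numbered arrays as pairs, the hybridisation controls were lower in MT in 4 of 4 pairs and the Gapdh and Actb controls in 0 of 4. The paired exact p was 0.125 for each, and an exact test of 4 pairs cannot give a smaller p.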

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

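The comparisons of splits and the tests of explanations in this part were chosen after the results were seen. The counts of genes were compared with those of the 35 ways to split the 8 arrays into 2 groups of 4. Only the real split gave 5088 genes past the threshold (1 of 35), and the highest count among the others was 0. The same held for the larger of the directions, with 2641 genes (1 of 35, highest other 0), and for the 630 genes changed at least 2-fold (1 of 35, highest other 0). The other splits mix groups that differ, which widens their spread. Of the 8 splits that part all 4 numbered pairs, as the real one does, only the real one gave any genes (highest other 0), but 8 splits are too few for a share under 0.05. For the 14 lists called by camera, 4 of 35 splits gave 14 or more lists and the highest other count was 14. The 3 other splits with as many all kept 3 arrays of each group together, and 16 of the 35 splits did so, with 8 to 14 lists called. The 18 splits that mixed the groups evenly called 6 lists at most. Of the 8 splits that part all pairs, the real one included, 2 gave as many lists and the highest other count was 14, while the remaining splits leave pairs together. The real split was therefore not alone in its number of lists. Splits that keep 3 arrays of each group together carry part of the contrast between groups, so a tie with them cannot tell chance from that contrast.

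A single array stood far from the other 3 of its group in 16 of 260 sets of 4 values, where chance marks about 1 in 20 sets, or 13. MT array 2 accounted for 5 of these and MT array 1 for 4. In MT array 2, Adipoq lay 2.26 above the mean of the other 3 on the log2 scale, Fabp4 1.48 above and Psmb8 0.44 above, while S100a8 lay at -0.64 and Mbp at -0.18 relative to the others. In MT array 1, Fos lay 0.33 and Pgk1 0.15 above the others, Cd4 lay at -0.10, and the 3' minus 5' value of Gapdh lay 0.17 above. In MT array 3, Tpi1 lay at -0.087. In wild type, Steap4 (0.41) and Scd1 (0.45) stood apart on array 4, Idh3a (-0.29) and Pgk1 (-0.13) on array 1, and Dcn (-0.30) and Mbp (0.21) on array 2. Outside the gene-level test, 2246 probe sets had several symbols or none, and 736 of them (32.8%) passed the threshold in a fit of all probe sets, 366 higher and 370 lower.

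The first pattern weighed is the fall of the 33 smooth muscle and matrix genes, whose median was -0.85. Fat carried with some wild-type pieces is argued against as the whole cause: the group coefficient of their mean level was -0.77 (SE 0.17) without and -0.79 (SE 0.26) with the mean adipocyte level as a term, with a 95% interval from -1.47 to -0.12. A larger epithelial share that lowered every other cell type alike would not raise macrophage genes. Among genes with a wild-type mean from 5 to 9, the 14 macrophage genes had a median of 0.51 and the 18 stromal genes one of -0.71. The rise of the macrophage genes itself argues against such a lowering. For the difference of 1.22, a permutation test over genes gave p = 1e-05, the smallest that 100000 permutations can give. The direction of both sets was known before, and correlated genes were shuffled as independent, so this p adds no support. Such a share beside an influx of macrophages is not settled. The 7 endothelial genes of that range had a median of -0.17, a difference of 0.54 from the stromal genes (permutation p = 0.0742). This test too shuffled correlated genes as independent. The endothelial genes were also dimmer, with a wild-type mean of 6.22 against 7.40, which can shrink a fold. A larger epithelial share beside such an influx, a different amount of muscle wall in the pieces and a change of the stroma with the transgene all stay open.

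The second pattern is the rise of interferon genes. More macrophages and lymphocytes in an unchanged state would raise those cells' genes at least as much, but at MT levels of at least 5 the 26 macrophage and lymphocyte genes had a median of 0.36 against 1.65 for the 19 interferon genes. The difference was -1.29, and 2 of the 26 lay above the interferon median. Levels were not matched beyond that floor. On the wild-type arrays the macrophage list read 6.41 to 6.99, above the interferon list at 5.95 to 6.22, and its median change was 0.51. These sizes argue against macrophages in an unchanged state as the source of the whole rise. The T cell list (5.10 to 5.13) and the B and plasma cell list (4.94 to 5.11) read nearer the background range there, which can shrink a fold. For lymphocytes the sizes therefore cannot decide. A permutation test over genes gave p = 1e-05, the smallest that 100000 permutations can give. It shuffled genes as if they were independent, so it does not measure the spread between arrays. The estimated correlations between genes were 0.41 in the interferon list and 0.52 in the macrophage list. More lymphocytes, leukocytes or epithelial cells in another state, and the transgene's own effect stay open. So do more neutrophils, although only 3 of 9 granulocyte genes were higher, S100a8 and S100a9 among them, and other cells can also make these 2. No label gives housing, infection or array batch, so a difference in these between the groups was not tested.

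The third pattern is the spread of adipocyte genes between arrays. The 8 genes deviated together within groups, with a mean correlation of 0.69 against at most 0.48 in 10000 random lists of matched level. Those lists were not matched for shared regulation. For comparison, the estimated correlation was 0.84 in the smooth muscle list and 0.03 in the T cell list. A varying amount of fat in the pieces may explain the spread, but the correlation cannot tell it from another shared source. Whether the MT pieces held less fat as a group stays open, since the mean of these genes differed by -0.91 (exact permutation p = 0.0571) and was lower in MT in 4 of 4 same-numbered pairs (paired exact p = 0.125, the smallest that 4 pairs can give). A smaller fat depot around the MT prostate and a difference in dissection would look alike, and neither was tested.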

How the results depend on the processing

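The alternatives were planned, with exceptions chosen after seeing the data: the removal of wild-type array 4 and MT array 2, and the p-values of single lists under another prior, array weights, unique-type probe sets, quantile normalization and median centring, and the paired exact tests. Leaving out single arrays gave 4476 to 4972 genes past the threshold, 2177 to 2406 higher, 2299 to 2566 lower, 611 to 669 at 2-fold and 12 to 15 lists. With the number as a replicate block, 5211 genes passed, 4914 of them shared with the unblocked fit in the same direction, and the block changed no call of a named gene or list. With median centring 2152 genes were higher and 3109 lower. The count moved by over 1.5 times for all probe sets, which are more numerous than genes (8552 past the threshold, 4089 higher, 4463 lower, 1025 at 2-fold), and for a minimum change of 0.5, a stricter test (877). Of 1096 values of named genes under the other alternatives, 1080 kept direction and side of the threshold, 13 lost the call, 1 gained it and 2 reversed. The reversals were Mbp averaged over probe sets (-0.0052) and Tpsb2 among unique-type probe sets (0.21, adjusted p = 0.0352, a gained call). Some sizes depended on the probe set rule by over 1.5 times while the call stayed. This held for 10 named genes averaged over probe sets and for 3 among unique-type probe sets. When single arrays were left out, 1002 of 1024 kept both. The RNA quality differences ran from -0.24 to -0.12 for Gapdh and from -0.25 to -0.13 for Actb without single arrays, on the same side of the threshold, and the paired exact p was 0.25 for both. Signals near the background range of 2.57 to 3.90, where 1163 genes had both group means under its top, limit what changes of low genes can show.

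The list calls depend on the correlation assumed between genes. With an estimated correlation 2 lists passed, proliferation and chemokines, and the adjusted p was 0.0872 for luminal keratins, 0.228 for glycolysis, 0.145 for endoplasmic reticulum folding, interferon response and antigen presentation, 0.0637 for immediate early genes and 0.406 for extracellular matrix, matrix proteases, mesenchymal regulators, smooth muscle, macrophage and granulocyte. Estimates from 6 residual degrees of freedom are themselves uncertain. The protease list lost its call with probe set averages (0.0899), unique-type probe sets (0.0574), the level filter (0.119) and members of a single list (0.102), and the mesenchymal list with probe set averages (0.0747), unique-type probe sets (0.134), the filter (0.377) and without the 2 arrays (0.0603). Without those 2 arrays, ERK output (0.0368) and complement (0.0368) passed, and with median centring complement (0.0423) and progenitor genes (0.0429) did. Without single arrays the adjusted p ran from 0.0205 to 0.0574 for proteases, 0.0134 to 0.067 for mesenchymal regulators, 0.0362 to 0.141 for ERK output, 0.0357 to 0.115 for complement and 0.0248 to 0.199 for adipocyte genes. For these lists the cause was not tested.

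The fry test asks whether a list's own genes move, on balance, one way, and does not compare them with other genes, so more lists passed. Its directional adjusted p was 1.16e-05 for prostate secretory and progenitor genes, 0.0068 for androgen response, 0.00432 for ERK output and nerve, 0.000762 for polyamine and housekeeping genes, 6.35e-05 for complement, 0.037 for T cell, 0.000199 for B and plasma cell, 0.0177 for erythroid, 0.00122 for other lobes, 0.00521 for epididymis, 0.00165 for bladder and 0.000399 for skeletal muscle. Its mixed test, for change in either direction, gave 1.04e-07 for prostate secretory, androgen response and complement genes, 2.17e-06 for basal, 4.2e-09 for progenitor, 4.99e-06 for ERK output, 2.25e-06 for FOXO, 6.38e-06 for SREBP, 6e-08 for polyamine, 2.79e-09 for oxidative phosphorylation, 6.61e-06 for housekeeping, 0.00125 for endothelium, 2.13e-07 for T cell, 1.99e-05 for B and plasma cell, 0.00623 for other lobes, 9.84e-05 for epididymis, 0.000394 for bladder, 3.79e-05 for skeletal muscle, 0.0412 for adipocyte, 0.000152 for nerve and 0.0098 for neuroendocrine genes.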

Other observations

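Genes were also grouped by the letters their symbols start with, a grouping chosen after seeing the data, and 210 such groups had at least 8 measured members. Some of their genes stand in the fixed lists too, among them 10 of 12 Cxcl and 6 of 9 Mcm genes. Of these, 13 passed in camera after adjustment, 6 higher and 7 lower, and 0 passed with an estimated correlation (smallest adjusted p = 0.501). Homeobox genes of the Hoxb cluster were higher for 6 of 9 (median 0.27, adjusted p = 0.0131), with Hoxb6 at 2.66 ± 0.13 (SE), Hoxb9 at 2.18 ± 0.16 and Hoxb5 at 1.41 ± 0.11. Toll-like receptors were higher for 5 of 9 (median 0.25, adjusted p = 0.0494), with Tlr2 at 1.57 ± 0.09 and Tlr3 at 1.24 ± 0.09. Macrophage genes were higher in the same arrays, 10 of 16 with a median of 0.51.

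Among the 7 groups called lower, the Tmed genes, cargo receptors of the early secretory route, were lower for 6 of 9 (median -0.54, adjusted p = 0.013), with Tmed10 at -0.96 ± 0.07 (SE). The Sec stem holds coat proteins of the same route beside unrelated genes, and 12 of 23 were lower and 4 higher (median -0.25, adjusted p = 0.0272), with Sec13 at -1.36 ± 0.08 and Sec24d at -1.27 ± 0.09. Of the aldehyde dehydrogenases (Aldh), 9 of 17 were lower and 1 higher (median -0.27, adjusted p = 0.00966), with Aldh1a7 at -2.48 ± 0.06. Ribosomal protein genes shifted by less at the median, which was -0.21 for both the Rps and the Rpl stem (camera adjusted p = 0.0131 for each). Of the Rps stem, which includes some kinases, 15 of 26 genes were lower, and of the Rpl stem 14 of 24. Rps6 fell by more, at -1.12 ± 0.07. The direction of each family median named here stayed when the arrays were quantile normalized again or centred on their medians. The Rps median was then -0.11 and -0.25, and the Rpl median -0.14 and -0.25.

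A few B cell genes read high on a single array. On MT array 2, which also read high for adipocyte genes, Ms4a1 read 6.36 and Cd79b 6.85, against 4.64 to 5.15 and 4.99 to 5.27 on the other MT arrays, while the SD over the 4 MT arrays was 0.05 for Ighm and 0.11 for Cd22. Itln1 read 8.26 and 7.36 on wild-type arrays 1 and 4, 4.97 and 5.54 on arrays 2 and 3, and 4.30 to 4.49 in MT. These genes were chosen after their values were seen.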
